A study of Mus musculus with 8 samples.

How the data were processed

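Counts per gene for the 4 Ubc9 libraries and the 4 H1 libraries were analysed as deposited, in a table for each comparison. Per the submitters' processing notes, the deposited counts were made by the authors with a set of tools that names cutadapt, STAR, HTSeq and DESeq2, on mm10. The step each tool was used for, its version, the annotation used for counting and whether counting used strand are not given in the sources used here. Per the labels, RNA was extracted with Trizol and selected on polyA beads, and libraries were made with the ScriptSeq v2 kit for the Ubc9 cells and the Lexogen SENSE V2 kit for the H1 cells. The H1 lines came from an earlier publication, per the labels. The tables hold 24421 gene symbols, of which 23376 were matched by name and 678 by an older name to GENCODE M21 (GRCm38) for coordinates, exonic length and GC content, and 367 were not matched.

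The groups, the tests, the gene lists, the rule for naming genes and a set of alternatives were fixed from the labels before the data were examined. Because the comparisons used different kits, each was fitted on its own 4 libraries with edgeR 4.0.16 in R 4.3.3. The fit used filterByExpr (minimum count 10, minimum total 15), TMM factors, a quasi-likelihood F test and Benjamini-Hochberg adjustment at 0.05. This left 16499 genes in the Ubc9 comparison and 14800 in the H1 comparison, with biological coefficients of variation of 0.255 and 0.239. CPM values use TMM-scaled library sizes. The interaction was tested in 1 fit of all 8 libraries, and overlap by a two-sided Fisher's exact test over genes tested in both. Within pairs of libraries the Spearman correlation of counts was 0.978 for Ubc9-depleted, 0.997 for Ubc9 control, 0.994 for H1 TKO and 0.976 for H1 control.

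Of 26 lists written from general knowledge, the list of mitochondrially encoded genes had 0 members in the tables, and the other 25 were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over lists. In the Ubc9 comparison 10 lists passed, 5 higher and 5 lower, and in the H1 comparison 9 passed, 6 higher and 3 lower. With the correlation estimated from the residuals 0 passed in each comparison in limma's camera, and 2 in each had an unadjusted p under 0.05. Named genes were the targeted genes, the 10 highest and 10 lowest log2 fold changes per comparison among genes that passed with a mean of at least 5 CPM and no overlap between groups, up to 4 members of each list, and 5 shared genes per direction. Some of the genes so named are left out of the text. Clone-named genes were passed over, 1 in all. Where a group had 0 counts a fold is given as a bound from 3 counts over the group, and with 1 to 3 counts as a ratio with a 95% counting interval.

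The alternatives fixed in this way were DESeq2 1.42.0, RLE factors, library totals alone, no filter, a 2-fold threshold, all 8 libraries in 1 fit, a replicate block, fry, an estimated correlation and leaving out each library. A lone library left in a group was assumed to vary like the libraries of the other group, so that leaving out a Ubc9 control takes the spread from the Ubc9-depleted pair and leaving out an H1 TKO library takes it from the H1 control pair. GC offsets (loess, span 0.5), leaving out chromosomes 6 and 8, lists without Ubc9-depleted library 1 or H1 control library 1, camera without each library for lists other than the 2-cell-stage genes, and the search of gene families with its test against genes of like level were chosen after seeing the data.

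In a self-test, counts were simulated from the fitted dispersions with 200 changed genes, 100 at 2-fold and 100 at 4-fold. The edgeR test recovered 63% and 75% of them in the Ubc9 design and 29% and 82% in the H1 design. Of the calls, 7.38% in the Ubc9 design (11 genes) and 11.9% in the H1 design (15 genes) were false, above the nominal 5%. The limit first set for this share was 10%, and it was raised to 15% after the H1 value was seen. A changed list was called in both designs, and 0 of 20 unchanged lists were called in each by limma's camera. Each gene was simulated independently, so this does not show how often camera calls unchanged lists whose genes are correlated. Reads, splicing, transposable elements and allele-level expression were not analysed here.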

Results

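Gene expression was measured by sequencing polyA-selected RNA from 8 libraries of mouse embryonic stem cells, which were grown for 3 to 4 passages in 2i/LIF, a medium that holds them in a naive pluripotent state. The libraries form 4 groups of 2. Ubc9-depleted cells of the v6.5 line were collected after 72 hours of doxycycline and set against control cells of the same line. Ubc9 is the E2 enzyme that attaches the small protein SUMO to its targets. H1 triple-knockout (H1 TKO) cells, which lack the linker histones encoded by Hist1h1c, Hist1h1d and Hist1h1e, were set against their own controls. The labels do not say whether the Ubc9 control cells received doxycycline, nor whether the 2 libraries of a group came from separate cultures. Every p-value of a single gene below therefore measures only the spread between libraries. The p-values of overlaps and gene families treat genes as independent draws and do not measure that spread. Those of camera set the genes of a list against other genes, at a preset or estimated correlation.

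Ubc9-depleted libraries 1 and 2 held 88410194 and 75972231 counts over genes, and Ubc9 control libraries 1 and 2 held 102780141 and 99269669. H1 TKO libraries 1 and 2 held 44441713 and 68445181 counts, and H1 control libraries 1 and 2 held 56032400 and 52960206. At these depths 3 counts correspond to between 0.0292 and 0.0675 CPM (counts scaled to library size). A pair of libraries stood apart from their partners. Ubc9-depleted library 1 had counts on 23462 of the 24421 genes, against 18584 to 19591 in the other Ubc9 libraries, and 84.4% of the 6248 genes with at most 1 count in each Ubc9 control carried a read in it at equal depth, against 29.2% in Ubc9-depleted library 2. H1 control libraries 1 and 2 differed with an SD of the log2 ratio per gene of 0.79, against 0.51 between the H1 TKO libraries. Member counts without Ubc9-depleted library 1 or H1 control library 1 are therefore given beside the gene lists of each single comparison, but not beside those of the interaction. A fit without a library filters genes anew, so it can test more or fewer members than the full fit.

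The first comparison addresses which genes change when SUMO conjugation is impaired. The genes that rose furthest after Ubc9 depletion included Zscan4d, a marker of the 2-cell embryo, which went from 3.66 ± 0.56 to 127 ± 4.62 CPM (mean ± SD, n = 2 libraries per group here and below), and its relatives Zscan4b, Zscan4f and Zscan4c, whose reads near-identical copies may share. Mmp12, a secreted metalloproteinase with 1.22 ± 0.024 CPM in the controls, rose by 6.47 ± 0.16 on the log2 scale (± SE, adjusted p = 5.3e-23, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Gria4, a glutamate receptor subunit, rose by 5.67 ± 0.19, Akr1c21, a hydroxysteroid dehydrogenase, by 5.49 ± 0.22, and Clec2g, a C-type lectin, by 5.34 ± 0.16 on the log2 scale. Cml2 and Col6a5, a collagen gene, complete the 10 highest genes with a mean of at least 5 CPM, with log2 fold changes of 4.80 and 4.65. Lefty2, a secreted inhibitor of Nodal signalling, fell by 3.31 ± 0.13, from 132 ± 2.84 to 13.2 ± 0.38 CPM. Rasgrp1, an activator of Ras, fell by 2.83 ± 0.18, Csf3r, the receptor of a granulocyte growth factor, by 2.82 ± 0.12, and Ngfr, a neurotrophin receptor, by 2.53 ± 0.12 on the log2 scale. Gstm3, Ap3b2, Ffar2, Fgf10, Pdzrn4 and Krt42 had log2 fold changes between -2.57 and -2.08. These 20 genes passed with each of the 4 libraries left out in turn.

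Of 16499 genes tested, 3479 were higher and 2467 lower in Ubc9-depleted cells at an adjusted p under 0.05 (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). The genes called higher had a median log2 fold change of 1.78 at a median of 2.43 CPM, against -0.46 at 49.6 CPM for the genes called lower. At low counts only large changes reach the threshold. Genes near 0 in both controls passed the filter only through the Ubc9-depleted libraries, so they could only be called higher. Of genes with a control mean under 0.5 CPM, 0 were called lower. Part of this asymmetry is therefore set by power and the filter. A change of at least 2-fold was seen in 2357 of the higher genes and 168 of the lower genes. These counts were 1808 and 368 without Ubc9-depleted library 1, 7122 and 247 without Ubc9-depleted library 2, 926 and 148 or 873 and 140 without Ubc9 control library 1 or 2, and 2183 and 80 with scaling by library totals. Among 3229 genes with a control mean under 0.5 CPM, 1428 rose, or 992 without Ubc9-depleted library 1. Scaling by library totals alone moved the median of all genes from 0.06 to 0.25 and gave 3983 higher and 1084 lower genes, so that 78.6% of calls were higher, against 58.5% with TMM. The counts were 3128 and 2519 without Ubc9-depleted library 1, 8428 and 4610 without Ubc9-depleted library 2, 1299 and 898 without Ubc9 control library 1, and 1230 and 795 without Ubc9 control library 2.

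In the list of 2-cell-stage genes, 31 of 34 tested members rose after Ubc9 depletion and none fell (31 also when adjusted over the list alone). Dux, a transcription factor that opens the 2-cell programme, rose from 0.047 ± 0.021 to 1.17 ± 0.30 CPM, a log2 fold change of 4.59 ± 0.90. Zfp365 rose by 1.03 ± 0.11 and Obox6, an oocyte homeobox gene, by 1.01 ± 0.17 on the log2 scale. The deubiquitinase Usp17le and Dux were chosen after their values were seen, and Usp17le rose by 4.50 ± 0.15, but near-identical copies may share its reads. The members that did not pass were Pramef6, Tdpoz1 and Tdpoz4, with log2 fold changes of 2.32, 1.01 and 1.23. The list's median log2 fold change was 3.47, and camera gave an adjusted p of 2.5e-47 against other genes (adjusted p = 0.0864 with an estimated correlation). Without the Zscan4, Usp17l, Tdpoz and Tcstv families, 18 of 19 members rose, with a median of 3.46 (limma camera adjusted p = 2.2e-27). The count was 31 without Ubc9-depleted library 1, 33 without Ubc9-depleted library 2, and 28 and 30 without Ubc9 control library 1 or 2.

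Germline genes, which act in meiosis or in silencing transposons, were mostly higher: 16 of 24 rose and 1 fell after Ubc9 depletion (18 and 2 adjusted over the list alone). Mael, a piRNA factor, rose from 1.64 ± 0.078 to 7.97 ± 0.0057 CPM, and Stk31 and Sycp1, chosen after their values were seen, rose by 1.70 ± 0.12 and 1.37 ± 0.11 on the log2 scale. The median log2 fold change was 0.82 (limma camera adjusted p = 2.3e-07; adjusted p = 0.468 with an estimated correlation). With Ubc9-depleted library 1, Ubc9-depleted library 2, Ubc9 control library 1 and Ubc9 control library 2 left out in turn, 16, 15, 9 and 9 germline genes rose. Among 18 fibroblast markers 11 rose and 2 fell (12 and 2 adjusted over the list alone), with a median fold change of 2.64 (limma camera adjusted p = 0.0048; adjusted p = 0.719 with an estimated correlation). The collagen genes Col1a1, Col3a1 and Col5a1, chosen after their values were seen, rose by 1.12 ± 0.16, 1.36 ± 0.16 and 0.66 ± 0.11, while Ctgf, a secreted matrix protein, fell by 0.51 ± 0.11 on the log2 scale. Dcn, a matrix proteoglycan, had a log2 fold change of 2.16, with adjusted p = 0.17 and 0.22 (edgeR) without Ubc9 control library 1 or 2. In the same order of libraries, 14, 14, 7 and 7 fibroblast markers rose.

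Integrated stress response genes rose in 11 of 24 cases and none fell (11 also adjusted over the list alone) after Ubc9 depletion. The stress transcription factor Atf3 rose from 2.25 ± 0.026 to 6.99 ± 0.87 CPM, and Cebpb had a log2 fold change of 1.33 ± 0.30, with adjusted p = 0.10 and 0.066 (edgeR) without Ubc9 control library 1 or 2. The median was 0.31 (limma camera adjusted p = 0.0053; adjusted p = 0.599 with an estimated correlation), and the camera call was lost without Ubc9-depleted library 1 (adjusted p = 0.0628) or 2 (adjusted p = 0.289). With Ubc9-depleted library 1, Ubc9-depleted library 2, Ubc9 control library 1 and Ubc9 control library 2 left out in turn, 11, 9, 3 and 3 of these genes rose. DESeq2 called 4 of them higher, and the fit with GC offsets, chosen after seeing the data, called 3. Of 27 clustered protocadherins, cell-surface genes of neurons, 6 rose and none fell (5 adjusted over the list alone), with a median of 0.51 (limma camera adjusted p = 0.0439; adjusted p = 0.719 with an estimated correlation). That share was near the share over all genes, where 3479 of 16499 rose. Pcdhga2 rose by 1.01 ± 0.31 on the log2 scale, with adjusted p = 0.46 and 0.23 (edgeR) without Ubc9 control library 1 or 2. In the same order of libraries, 6 of 27, 35 of 51, 1 of 52 and 1 of 52 tested protocadherins rose, with medians of 0.45, 3.56, 2.95 and 3.35, and limma camera gave adjusted p = 0.0878 without Ubc9-depleted library 1 and 0.0548 and 0.0628 without Ubc9 control library 1 or 2.

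S-phase genes were lower: 11 of 18 fell and none rose after Ubc9 depletion (13 adjusted over the list alone), with a median log2 fold change of -0.36, or -0.17 with scaling by library totals (limma camera adjusted p = 1.4e-06; adjusted p = 0.719 with an estimated correlation). Ccne1, the cyclin that starts DNA replication, fell from 135 ± 3.24 to 66.7 ± 2.54 CPM, and Rrm2, a subunit of ribonucleotide reductase, fell by 0.86 ± 0.13 on the log2 scale. With Ubc9-depleted library 1, Ubc9-depleted library 2, Ubc9 control library 1 and Ubc9 control library 2 left out in turn, 11, 14, 5 and 5 fell. Of 18 G2/M genes 12 fell and none rose (14 adjusted over the list alone), with a median of -0.40, or -0.20 with scaling by library totals (limma camera adjusted p = 1.4e-06; adjusted p = 0.719 with an estimated correlation). The mitotic motor Kif11 fell by 0.63 ± 0.13 and Top2a, a topoisomerase, by 0.80 ± 0.13 on the log2 scale. In the same order of libraries 11, 17, 0 and 0 G2/M genes fell. Without Ubc9 control library 1 or 2 the adjusted p was 0.14 and 0.25 for Kif11 and 0.21 and 0.23 for Top2a (edgeR).

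Chromatin repressors of the 2-cell programme were lower in 11 of 25 cases and higher in none after Ubc9 depletion (12 adjusted over the list alone), with a median of -0.30, or -0.11 with scaling by library totals (limma camera adjusted p = 3.7e-04; adjusted p = 0.719 with an estimated correlation). Over all genes 2467 of 16499 fell, but genes called lower had a median of 49.6 CPM, so that share may be too low for lists of highly expressed genes. The fixed lists, those of S-phase and G2/M genes included, were not set against genes of like level. Uhrf1, which guides maintenance DNA methylation, fell from 440 ± 12.1 to 248 ± 19.9 CPM, and Pcgf6, a subunit of a Polycomb complex, fell from 57.8 ± 2.11 to 38.4 ± 0.68 CPM. With Ubc9-depleted library 1, Ubc9-depleted library 2, Ubc9 control library 1 and Ubc9 control library 2 left out in turn, 9, 19, 2 and 2 fell. Among 22 SUMO pathway genes 4 fell and 1 rose (the same counts adjusted over the list alone), with a median of -0.15 that turned to 0.04 when libraries were scaled by their totals (limma camera adjusted p = 0.0266; adjusted p = 0.739 with an estimated correlation, and 0.0833 without Ubc9-depleted library 1). Senp6, a SUMO protease, rose by 0.81 ± 0.13 and Ranbp2, a SUMO ligase of the nuclear pore, fell by 0.56 ± 0.13 on the log2 scale, with adjusted p = 0.10 and 0.24 without Ubc9 control library 1 and 0.093 and 0.44 without Ubc9 control library 2 (edgeR). In the same order of libraries 6, 11, 1 and 1 SUMO pathway genes fell.

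Of 13 mesendoderm genes 7 fell and 1 rose after Ubc9 depletion (7 and 3 adjusted over the list alone), with a median of -0.45, or -0.25 with scaling by library totals (limma camera adjusted p = 0.0176; adjusted p = 0.719 with an estimated correlation). Lefty2 led the fall. Lefty1 and Eomes, a transcription factor of the primitive streak, fell by 2.20 ± 0.57 and 0.45 ± 0.15 on the log2 scale, with adjusted p = 0.27 and 0.28 without Ubc9 control library 1 and 0.18 and 0.24 without Ubc9 control library 2 (edgeR). With Ubc9-depleted library 1, Ubc9-depleted library 2, Ubc9 control library 1 and Ubc9 control library 2 left out in turn, 7, 7, 3 and 4 fell, 0, 7, 0 and 0 rose, the median was -0.64, 0.28, 0.30 and 0.10, and limma camera lost the call without Ubc9-depleted library 2 (adjusted p = 0.507).

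The other lists did not pass camera after Ubc9 depletion, with adjusted p from 0.0576 to 0.867, and their counts of higher and lower members follow, with counts adjusted over the list alone as list-alone. Among 20 naive pluripotency genes 2 rose and 6 fell (list-alone 2 and 7). Dppa3, a maternal factor that is high in naive cells, fell by 1.39 ± 0.12 on the log2 scale. The naive list's median of -0.03 turned to 0.15 with scaling by totals, and its camera adjusted p of 0.0576 became 0.0019, 0.0050 and 0.0080 without Ubc9-depleted library 2, Ubc9 control library 1 or Ubc9 control library 2, and 0.0426 with GC offsets (limma). Among 11 core pluripotency genes 2 rose and 1 fell (list-alone 2 and 1), with Dnmt3l, a cofactor of DNA methylation, up by 1.57 ± 0.12, and the core list's median was 0.03, or -0.11 with GC offsets. Among 13 formative and primed genes 4 rose and 4 fell (list-alone 4 and 4). Pou3f1 rose by 2.06 ± 0.21 and Otx2 fell by 1.89 ± 0.11, both transcription factors of the primed state. The formative list's median (0.13) and mean (0.12) were above 0 where camera's direction was down, and the median was -0.04 with GC offsets. Without Ubc9-depleted library 1, Ubc9-depleted library 2, Ubc9 control library 1 and Ubc9 control library 2, the naive list had 3, 2, 0 and 0 higher and 5, 8, 3 and 3 lower members, the core list 3, 1, 2 and 1 higher and 1, 4, 1 and 0 lower, and the formative list 3, 4, 1 and 1 higher and 4, 6, 4 and 2 lower.

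Lineage markers went both ways after Ubc9 depletion. Of 14 neuroectoderm genes 5 rose and 2 fell (list-alone 5 and 2), with Tubb3, a neuronal tubulin, down by 0.55 ± 0.11 on the log2 scale. The neuroectoderm list's median of 0.56 was -0.01 without Ubc9-depleted library 1. Of 16 primitive endoderm genes 8 rose and 1 fell (list-alone 9 and 1). Cubn, an endocytic receptor, rose by 4.68 ± 0.81 and the laminin gene Lama1 fell by 0.80 ± 0.12. Of 16 trophectoderm genes 2 rose and 4 fell (list-alone 2 and 4), with Tfap2a down by 0.73 ± 0.12. The trophectoderm list's median (0.28) and mean (0.23) were above 0 where camera's direction was down. Of 30 imprinted genes 11 rose and 6 fell (list-alone 13 and 6). Magel2 and Igf2, a growth factor, rose by 4.68 ± 0.71 and 2.53 ± 0.24, and Plagl1 fell by 1.05 ± 0.13. Of 9 Rhox genes 1 rose, Rhox13 from 5.68 ± 0.13 to 13.1 ± 1.60 CPM, and 1 fell (list-alone 1 and 1). Without Ubc9-depleted library 1, Ubc9-depleted library 2, Ubc9 control library 1 and Ubc9 control library 2, higher members numbered 5, 9, 2 and 2 for neuroectoderm, 7, 11, 3 and 4 for primitive endoderm, 1, 5, 0 and 0 for trophectoderm and 13, 14, 4 and 4 for imprinted genes. In that order, 5, 7, 3 and 3 imprinted, 4, 4, 1 and 1 trophectoderm and 3, 3, 0 and 0 Rhox genes were lower.

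Of 22 p53 targets 8 rose and 1 fell after Ubc9 depletion (list-alone 8 and 1), the latter being the cell-cycle inhibitor Cdkn1a, down by 0.61 ± 0.12 on the log2 scale. Of 18 interferon response genes 6 rose and 2 fell (list-alone 8 and 2), with Oas1a, an antiviral enzyme, down by 0.80 ± 0.15. Of 8 histone H1 genes 1 rose and 3 fell (list-alone 1 and 3): H1fx rose by 0.51 ± 0.13, and Hist1h1b, Hist1h1d and Hist1h1a had log2 fold changes of -0.88 ± 0.17, -0.65 ± 0.14 and -0.54 ± 0.19. The histone H1 calls were lost without Ubc9 control library 1 for Hist1h1b, Hist1h1d and Hist1h1a (adjusted p = 0.26, 0.34 and 0.76, edgeR), and for H1fx without Ubc9-depleted library 1 or Ubc9 control library 2 (adjusted p = 0.28 and 0.097, edgeR). Hist1h1a was also lost without Ubc9-depleted library 1 (adjusted p = 0.075, edgeR), and Hist1h1a and H1fx were lost with DESeq2 (adjusted p = 0.17 and 0.096). In the order of libraries used above, 1, 4, 2 and 0 histone H1 genes rose and 2, 3, 0 and 3 fell. The list's median of -0.003 was 0.19 with scaling by totals. Of 4 Y-linked genes 1 rose, the histone demethylase Kdm5d, from 2.43 ± 0.17 to 12.1 ± 1.23 CPM, and 2 rose without Ubc9-depleted library 1. Core histone genes had 3 higher and 4 lower of 50 (list-alone 1 and 4), with Hist1h2bn down by 1.04 ± 0.12. Because RNA was selected on polyA beads, counts of the H1 and core histone genes may leave out transcripts without a polyA tail. Hox genes had 6 higher and 4 lower of 35 (list-alone 5 and 4), and cytosolic ribosomal protein genes 3 higher and 1 lower of 77 (list-alone 0 and 0). For core histone genes (median 0.28) and Hox genes (median 0.27) the median was above 0 where camera's direction was down, and it was -0.53 and -0.43 without Ubc9-depleted library 1. Without Ubc9-depleted library 1, Ubc9-depleted library 2, Ubc9 control library 1 and Ubc9 control library 2, higher members numbered 8, 7, 0 and 1 for p53 targets, 3, 14, 2 and 1 for interferon genes, 1, 28, 0 and 1 for core histones, 5, 18, 0 and 1 for Hox genes and 21, 1, 0 and 0 for ribosomal protein genes. In that order, 14, 4, 4 and 6 core histone, 12, 9, 3 and 0 Hox and 6, 10, 1 and 0 ribosomal protein genes were lower. The core histone list passed limma camera without Ubc9-depleted library 1 (adjusted p = 2.8e-04).

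The second comparison sets H1 TKO cells against their controls, so H1 loss cannot be told apart from any other difference between these lines. It addresses which genes differ in cells without the linker histones encoded by Hist1h1c, Hist1h1d and Hist1h1e. These genes lie on chromosome 13 (GRCm38), from 23738808 to 23740367 on the plus strand, from 23553262 to 23560686 on the plus strand and from 23620629 to 23622558 on the minus strand. Hist1h1c had 0 counts in both H1 TKO libraries and 100 and 102 in the controls, Hist1h1d 0 against 159 and 231, and Hist1h1e 0 against 115 and 161. With the floor of 3 counts over the H1 TKO group they were at least 69.7-fold, 135-fold and 95.3-fold lower. Such floors and the counting intervals below cover counting error only. Counts of linker histone genes may also leave out transcripts without a polyA tail, since RNA was selected on polyA beads. H1f0, the replacement linker histone, rose from 48.9 ± 9.90 to 417 ± 21.3 CPM, a log2 fold change of 3.09 ± 0.23 (adjusted p = 5.9e-04, edgeR). Hist1h1t, the testis linker histone, had 33 counts against 0, at least 10.6-fold higher, and lost its call without H1 TKO library 1 (adjusted p = 0.13, edgeR). Of the 8 linker histone genes tested, these 2 rose and the 3 targeted ones fell (list-alone 2 and 3), and the list did not pass limma camera (adjusted p = 0.415). Leaving out H1 TKO library 1, H1 TKO library 2, H1 control library 1 and H1 control library 2 in turn, 1, 1, 2 and 4 linker histone genes rose and 3, 3, 5 and 3 fell.

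**Figure D1:**
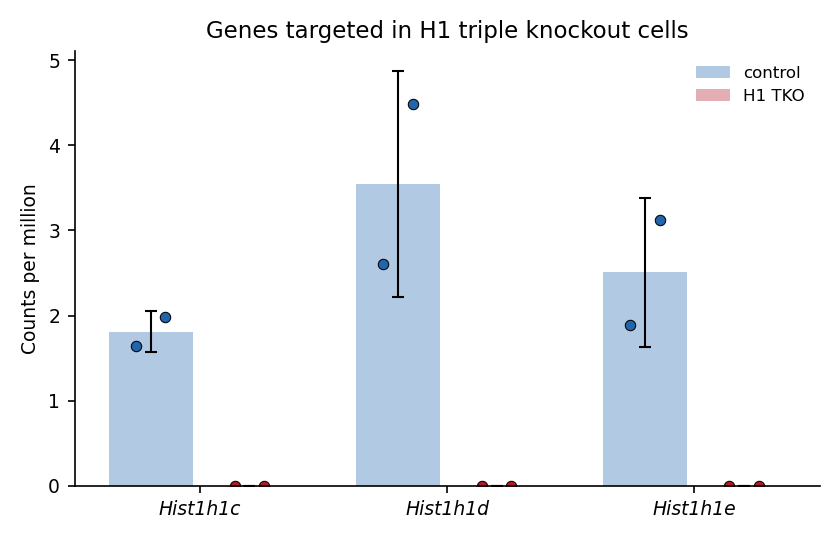
CPM of the genes targeted in H1 TKO cells, with bars for the mean of 2 libraries, whiskers for the SD and a point per library. Hist1h1c, Hist1h1d and Hist1h1e had 0 counts in both H1 TKO libraries and a total of 202, 390 and 276 in the controls.

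Among genes with a mean of at least 5 CPM, those that rose furthest in H1 TKO cells included Runx1, a transcription factor of blood formation, which went from 0.13 ± 0.098 to 21.0 ± 1.84 CPM, a log2 fold change of 7.29 ± 0.46. Mall rose by 7.92 ± 0.71 on the log2 scale and Adh1, an alcohol dehydrogenase, by 7.24 ± 0.48. Chrna4, a nicotinic receptor subunit, rose from 1.00 ± 0.093 to 76.1 ± 6.93 CPM, and H2-Eb1, an MHC class II chain, from 0.34 ± 0.040 to 18.3 ± 0.76 CPM. Spint5, Serpina3m, Dppa1 and Chl1 had log2 fold changes from 5.76 to 6.45. Mest, an imprinted gene on chromosome 6, fell from 283 ± 20.4 to 10.5 ± 0.66 CPM. The metallothionein Mt4, on chromosome 8, fell by 8.86 ± 0.62 on the log2 scale. Foxn4, Rac2, Nkx1-2, Padi2, Grb7 and Dmrt1 had log2 fold changes between -6.30 and -4.25. These genes passed with each of the 4 libraries left out in turn (edgeR).

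Of 14800 genes tested, 1271 were higher and 1247 lower in H1 TKO cells at an adjusted p under 0.05 (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), 1068 and 1019 of them by at least 2-fold. The 2-fold counts were 636 and 532 or 617 and 488 without H1 TKO library 1 or 2, and 1531 and 1464 or 1682 and 1524 without H1 control library 1 or 2. The median log2 fold change was 1.90 among the higher and -1.52 among the lower genes. Chromosomes 6 and 8 held 369 of the lower and 81 of the higher genes, and genes of at least 2 CPM had a median log2 fold change of -0.47 on chromosome 6 and -0.55 on chromosome 8. Without genes of chromosomes 6 and 8, a restriction chosen after seeing the data, 1190 were higher and 878 lower. The counts were 636 and 532 without H1 TKO library 1, 617 and 488 without H1 TKO library 2, 3610 and 3505 without H1 control library 1, and 3994 and 4038 without H1 control library 2.

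**Figure D2:**
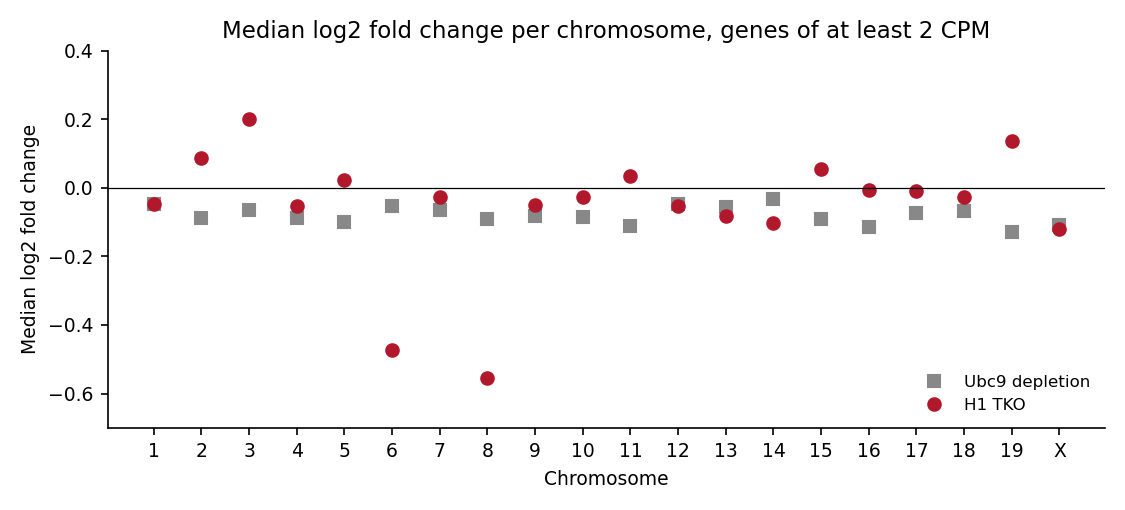
Median log2 fold change per chromosome among genes with a mean of at least 2 CPM, with a square per chromosome for Ubc9 depletion and a circle for H1 TKO. In H1 TKO cells chromosomes 6 and 8 stood at -0.47 and -0.55.

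Of 31 2-cell-stage genes tested, 26 rose and none fell in H1 TKO cells (27 adjusted over the list alone). Zscan4d rose from 1.13 ± 1.00 to 23.5 ± 0.50 CPM, a log2 fold change of 4.35 ± 0.58, and Zfp352, a zinc finger gene of the 2-cell embryo, rose by 5.46 ± 0.71. Usp17le, chosen with these genes after their values were seen, rose by 3.74 ± 0.26 on the log2 scale, and near-identical copies may share the reads of Zscan4d and Usp17le. Gm5662 and Zfp365 rose by 2.26 ± 0.39 and 1.36 ± 0.22, the latter with adjusted p = 0.076 without H1 TKO library 1 (edgeR). Pramef6 rose too, with 62 counts in the H1 TKO libraries and 0 in the controls, but was lost without H1 TKO library 2 (adjusted p = 0.080, edgeR). Members that did not pass were Dux (adjusted p = 0.499, edgeR) and Gm8300, Obox6, Ubtfl1 and Usp17ld, with log2 fold changes of 2.13, -0.46, 2.08 and 3.26. The median log2 fold change was 4.02, also with Pramef6 at its bound (limma camera adjusted p = 3.7e-29; adjusted p = 0.174 with an estimated correlation). Without the Zscan4, Usp17l, Tdpoz and Tcstv families, 13 of 17 members rose, with a median of 3.30 (limma camera adjusted p = 3.6e-12). The count of higher members was 29 without H1 control library 1 and 27 without H1 control library 2, where 1 member fell in each case, and 22 without H1 TKO library 1 or 2.

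**Figure D3:**
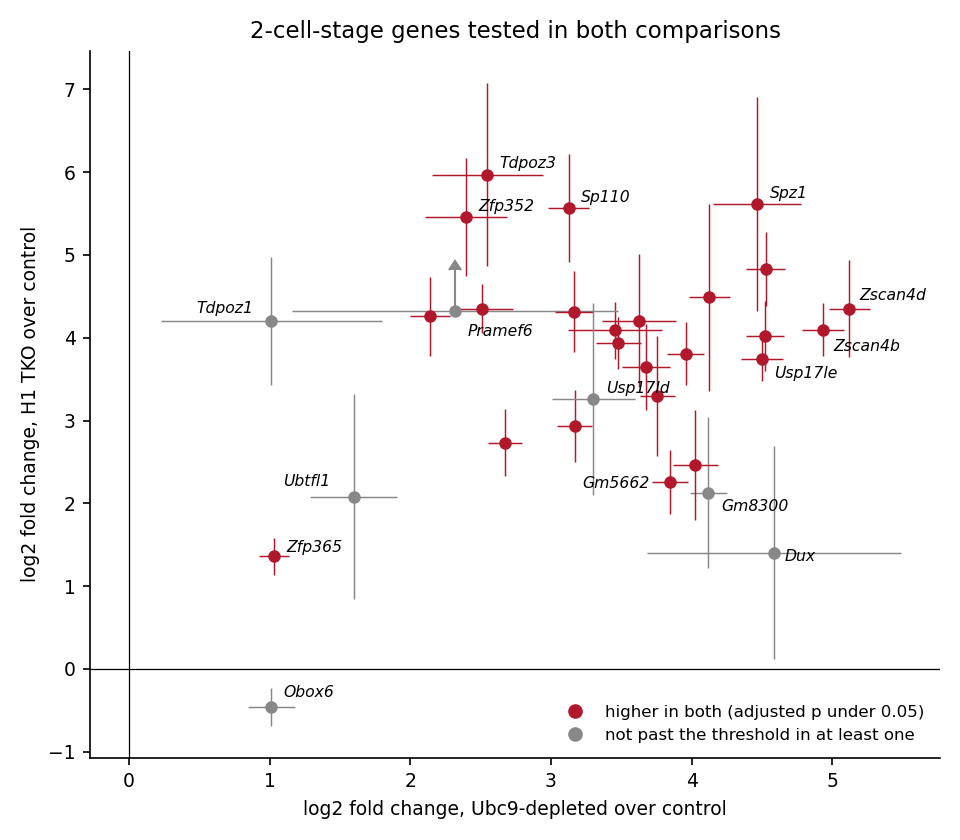
Log2 fold change of each 2-cell-stage gene after Ubc9 depletion (horizontal) and in H1 TKO cells (vertical), with lines of 1 SE and an arrow where Pramef6 is drawn at its lower bound. Of 31 genes tested in both comparisons, 24 were higher in both.

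The Rhox cluster, homeobox genes of the reproductive tract and placenta on the X chromosome, was higher in H1 TKO cells: 5 of 6 tested members rose (5 adjusted over the list alone). Rhox9 rose from 0.80 ± 0.28 to 7.82 ± 0.28 CPM and Rhox5 from 16.3 ± 2.85 to 53.4 ± 8.88 CPM. The median log2 fold change was 2.84 (limma camera adjusted p = 2.8e-07; adjusted p = 0.364 with an estimated correlation). Leaving out H1 TKO library 1, H1 TKO library 2, H1 control library 1 and H1 control library 2 in turn, it was 2.84, 2.58, 3.13 and 2.56. Of 16 trophectoderm genes 6 rose and 1 fell (8 and 1 adjusted over the list alone), with a median of 1.37 (limma camera adjusted p = 2.9e-04; adjusted p = 0.612 with an estimated correlation). The members that rose include epithelial keratins: Krt18 went from 6.72 ± 1.66 to 76.4 ± 4.94 CPM and Krt7 from 0.94 ± 0.010 to 13.4 ± 1.24 CPM. Tfap2c, a trophoblast transcription factor, fell by 1.07 ± 0.20 on the log2 scale, with adjusted p = 0.25 and 0.29 (edgeR) without H1 TKO library 1 or 2. With H1 TKO library 1, H1 TKO library 2, H1 control library 1 and H1 control library 2 left out in turn, 5, 5, 8 and 8 trophectoderm genes rose, and the fall was lost without either H1 TKO library.

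Of 24 germline genes 6 rose and 1 fell in H1 TKO cells (8 and 1 adjusted over the list alone), with a median of 0.74 (limma camera adjusted p = 0.0122; adjusted p = 0.612 with an estimated correlation, and 0.229 without H1 control library 2). Tex101, a germ cell surface protein, rose from 0.33 ± 0.050 to 6.93 ± 0.95 CPM and Brdt, a testis bromodomain protein, from 1.23 ± 0.65 to 6.30 ± 0.87 CPM. Stra8, a regulator of meiotic entry on chromosome 6, fell by 2.09 ± 0.21 on the log2 scale. Of 22 p53 targets 3 rose and none fell (7 and 1 adjusted over the list alone), among them the kinase gene Plk2 by 1.78 ± 0.21, with a median of 0.58 (limma camera adjusted p = 0.0293; adjusted p = 0.612 with an estimated correlation, and 0.0935 without H1 TKO library 1). With H1 TKO library 1, H1 TKO library 2, H1 control library 1 and H1 control library 2 left out in turn, 4, 4, 14 and 10 germline genes and 1, 2, 14 and 11 p53 targets rose. The 78 cytosolic ribosomal protein genes had a median of 0.48 (limma camera adjusted p = 2.0e-04; adjusted p = 0.672 with an estimated correlation). Only Rpl21 passed among them, by 0.78 ± 0.21, and none did when adjusted over the list alone, without H1 TKO library 1 (Rpl21 adjusted p = 0.33, edgeR) or without H1 TKO library 2 (adjusted p = 0.55, edgeR). Without H1 control library 1 or 2, 40 and 70 ribosomal protein genes rose, with medians of 0.27 and 0.82, and 9 rose with DESeq2 and 29 with GC offsets. Their median log2 ratio of H1 control library 1 to H1 control library 2 was -0.59.

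Of 13 formative and primed genes 4 fell and 2 rose in H1 TKO cells (5 and 2 adjusted over the list alone), with a median of -0.98 (limma camera adjusted p = 0.0387; adjusted p = 0.612 with an estimated correlation). Tcf15, a transcription factor of early exit from the naive state, fell from 12.3 ± 0.037 to 1.88 ± 0.089 CPM, and Grhl2, an epithelial transcription factor, rose from 0.80 ± 0.28 to 4.83 ± 0.80 CPM. Of 11 mesendoderm genes 4 fell and 1 rose (5 and 1 adjusted over the list alone), with a median of -1.31 (limma camera adjusted p = 0.0423; adjusted p = 0.612 with an estimated correlation). Lefty2 fell from 53.6 ± 8.50 to 3.57 ± 0.85 CPM, whereas Eomes rose by 1.15 ± 0.21 on the log2 scale, with adjusted p = 0.14 and 0.16 (edgeR) without H1 TKO library 1 or 2. Without H1 TKO library 1, H1 TKO library 2 and H1 control library 2, limma camera gave adjusted p = 0.113, 0.119 and 0.251 for the formative list and 0.182, 0.0768 and 0.234 for the mesendoderm list. With GC offsets the formative list had a limma camera adjusted p of 0.0668. Leaving out H1 TKO library 1, H1 TKO library 2, H1 control library 1 and H1 control library 2 in turn, 1, 3, 7 and 6 formative and 3, 2, 6 and 5 mesendoderm genes fell. Of 4 Y-linked genes 2 fell (3 adjusted over the list alone), with a median of -2.31 (limma camera adjusted p = 0.0387; adjusted p = 0.612 with an estimated correlation, 0.0573 with GC offsets and 0.435 without H1 control library 1). Ddx3y, a helicase gene, had 30 and 72 counts in the H1 TKO libraries and 604 and 118 in H1 control libraries 1 and 2, and Uty fell by 2.74 ± 0.42. With H1 control library 2 left out, 4 Y-linked genes fell, and 2 fell with any other library left out.

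**Figure D4:**
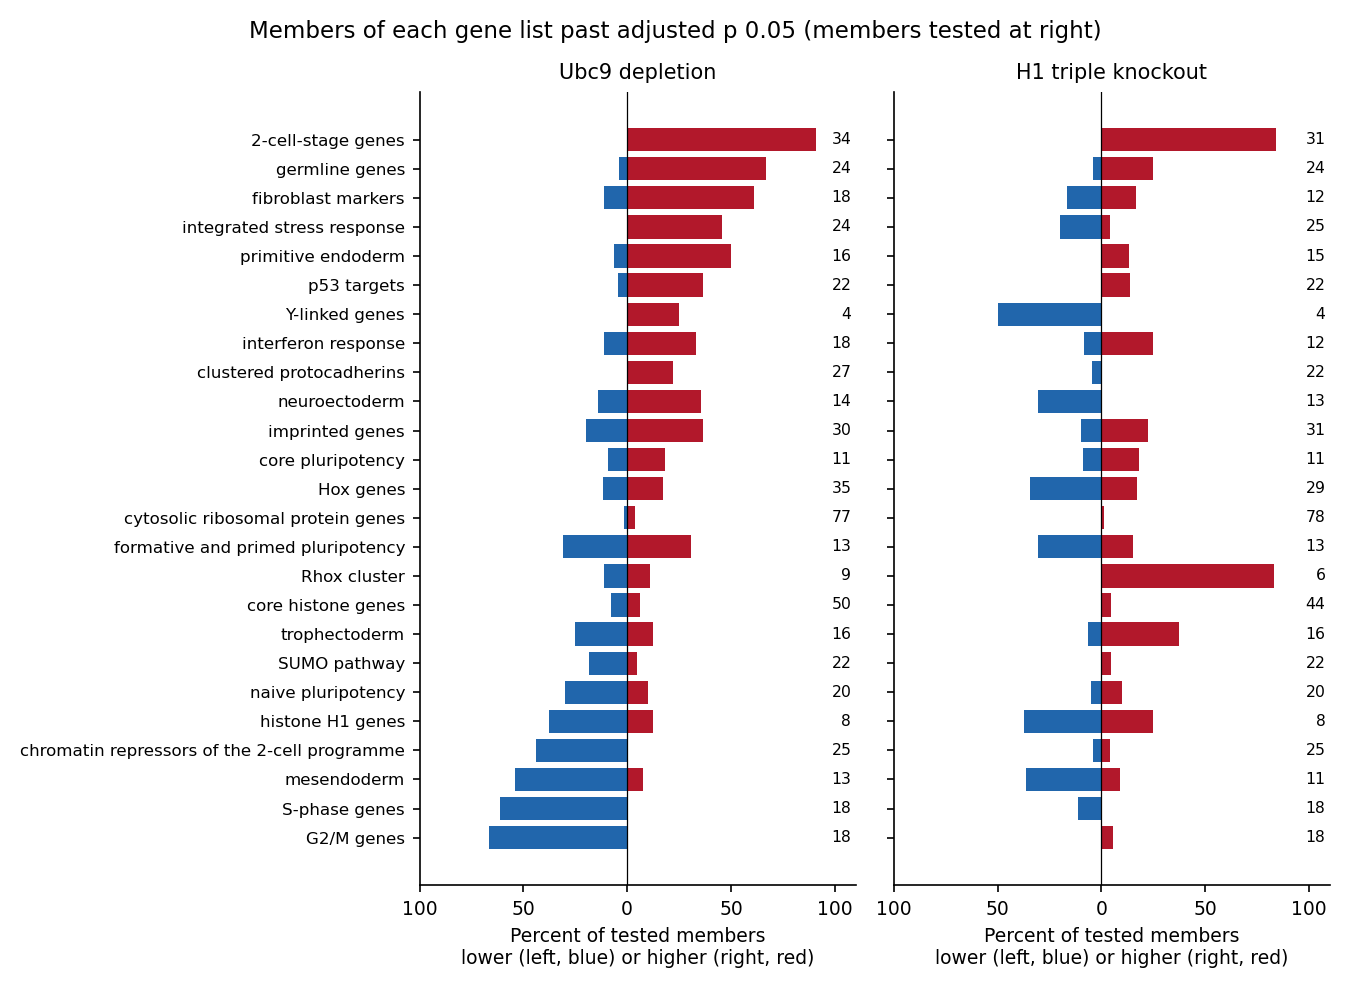
Percent of the tested members of each gene list that were higher (right) or lower (left) after Ubc9 depletion and in H1 TKO cells, with the number tested at the right of each bar. Of 2-cell-stage genes, 31 of 34 were higher after Ubc9 depletion and 26 of 31 in H1 TKO cells.

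The other lists did not pass camera in H1 TKO cells, with adjusted p from 0.103 to 0.645. Of 11 core pluripotency genes 2 rose and 1 fell (list-alone 3 and 1). Lin28a, an RNA-binding protein, fell by 3.75 ± 0.28 on the log2 scale and Dnmt3l rose from 20.8 ± 5.56 to 130 ± 5.91 CPM. Of 20 naive pluripotency genes 2 rose and 1 fell (list-alone 2 and 1), with Tfcp2l1, a naive-state transcription factor, up by 1.61 ± 0.19. Of 13 neuroectoderm genes none rose and 4 fell (list-alone 1 and 4), with Sox11, a neural transcription factor, down by 1.77 ± 0.26. Of 15 primitive endoderm genes 2 rose (list-alone 3 and 1), with Dab2, an endocytic adaptor, up by 2.65 ± 0.33. Of 31 imprinted genes 7 rose and 3 fell (list-alone 8 and 5): H19, a non-coding RNA, had 508 counts against 0 in the controls, at least 163-fold higher, and Mest fell as given above. Without H1 TKO library 1, H1 TKO library 2, H1 control library 1 and H1 control library 2, higher members numbered 1, 1, 7 and 7 in the core list, 1, 1, 7 and 11 in the naive list, 0, 0, 3 and 2 in the neuroectoderm list, 1, 1, 3 and 3 in the primitive endoderm list and 2, 2, 12 and 11 in the imprinted list. In that order, 1, 1, 1 and 3 core, 0, 0, 3 and 4 naive and 2, 1, 5 and 8 imprinted genes were lower.

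Hox genes went both ways in H1 TKO cells, 5 higher and 10 lower of 29 (list-alone 5 and 11). Hoxd8 rose from 0.59 ± 0.18 to 12.2 ± 1.10 CPM and Hoxa4, on chromosome 6, fell from 2.37 ± 0.32 to 0.17 ± 0.17 CPM. Of 25 integrated stress response genes 1 rose and 5 fell (list-alone 1 and 5), among them Mthfd2, a mitochondrial folate enzyme encoded on chromosome 6, which fell by 2.06 ± 0.19. Of 18 S-phase genes none rose and 2 fell (list-alone 0 and 2), one being the replication helicase subunit Mcm2 on chromosome 6, which fell by 1.52 ± 0.20. These last lists passed limma camera without H1 control library 1 (adjusted p = 0.0113 for stress response and 0.0348 for S-phase genes). Of 18 G2/M genes 1 rose, Aurka by 0.67 ± 0.19 (list-alone 0; adjusted p = 0.54 and 0.59 without H1 TKO library 1 or 2, edgeR). Of 12 interferon response genes 3 rose and 1 fell (list-alone 5 and 2), with Xaf1 up by 1.93 ± 0.22. Of 12 fibroblast markers 2 rose and 2 fell (list-alone 6 and 3): Mmp2 and Fbn1, which act in the extracellular matrix, rose by 3.14 ± 0.34 and 2.11 ± 0.31, and Pdgfrb fell by 2.06 ± 0.32. Without H1 TKO library 1, H1 TKO library 2, H1 control library 1 and H1 control library 2, higher and then lower members numbered 3, 3, 5 and 7 and 9, 5, 9 and 11 for Hox genes, 0, 0, 2 and 7 and 1, 2, 13 and 8 for stress response genes and 0, 0, 2 and 3 and 1, 1, 7 and 6 for S-phase genes. In that order they numbered 0, 0, 5 and 4 and 0, 0, 3 and 8 for G2/M genes, 1, 1, 6 and 5 and 0, 0, 2 and 1 for interferon genes and 2, 2, 7 and 8 and 1, 1, 4 and 2 for fibroblast markers.

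Of 22 SUMO pathway genes 1 rose and none fell in H1 TKO cells (list-alone 1 and 0). That list's median was -0.10 where its mean was 0.08 and camera's direction was up. Of 25 chromatin repressors of the 2-cell programme 1 rose and 1 fell (list-alone 0 and 1): Cbx3, a heterochromatin protein encoded on chromosome 6, fell by 1.97 ± 0.26 on the log2 scale, and Setdb1, a histone methyltransferase, rose by 0.69 ± 0.18, with adjusted p = 0.51 and 0.61 (edgeR) without H1 TKO library 1 or 2. Of 44 core histone genes 2 rose (list-alone 1) and of 22 clustered protocadherins 1 fell (list-alone 1). Without H1 TKO library 1, H1 TKO library 2, H1 control library 1 and H1 control library 2, higher and then lower members numbered 1, 1, 9 and 6 and 0, 0, 2 and 9 for SUMO pathway genes, 0, 0, 6 and 6 and 1, 1, 6 and 12 for chromatin repressors, 1, 0, 3 and 3 and 0, 0, 2 and 0 for core histone genes and 0, 0, 0 and 0 and 0, 1, 4 and 2 for protocadherins.

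The third comparison asks how far the differences after Ubc9 depletion and those in H1 TKO cells overlap. Among 14578 genes tested in both, 530 were higher in both against 225 from independent lists of those sizes (odds ratio 3.98, 95% interval 3.51 to 4.50, two-sided Fisher's exact test p = 3.8e-100). Another 381 were lower in both against 207 (odds ratio 2.44, 95% interval 2.14 to 2.78, Fisher's exact test p = 9.2e-38). Genes near 0 in all controls passed both filters only through the Ubc9-depleted and H1 TKO libraries, so they could only be called higher. The counts from independent lists take no account of this or of expression level, so part of the excess may come from it. Lefty2 fell in both, as did Rasgrp1 (-2.83 ± 0.18 and -4.03 ± 0.39), Nkx1-2, a homeobox gene (-2.67 ± 0.33 and -4.78 ± 0.28), and Ap3b2, an adaptor of vesicle transport in neurons (-2.40 ± 0.12 and -3.43 ± 0.35), with log2 fold changes for Ubc9 depletion and then H1 TKO. Nphs1os fell in both as well, but it is antisense to Nphs1, and whether counting used strand is not stated, so its reads cannot be assigned. Its Ubc9 call was lost without Ubc9 control library 1 or 2 (adjusted p = 0.58 and 0.65, edgeR). Mmp12 rose in both, with 164 counts against 1 in the H1 libraries, a ratio of 158 (95% counting interval 28.0 to 6292). Apoh, a plasma glycoprotein, had a ratio of 76.2 after Ubc9 depletion (95% counting interval 20.7 to 636) and was at least 58.3-fold higher in H1 TKO cells. The Ubc9 call of Apoh was lost without Ubc9 control library 1 or 2 (adjusted p = 0.074 and 0.28, edgeR). After Ubc9 depletion Klhl30, Jph2 and Esrrg had ratios of 73.1 (95% counting interval 19.8 to 611), 68.8 (23.2 to 337) and 70.5 (23.7 to 345), each with 3 or fewer control counts. Each lost its call without Ubc9 control library 1 (adjusted p = 0.10, 0.17 and 0.13) and without H1 TKO library 1 (adjusted p = 0.23, 0.19 and 0.098, edgeR). Klhl30 and Esrrg were also lost without Ubc9 control library 2 (adjusted p = 0.33 and 0.086), and Klhl30 in H1 TKO cells without H1 control library 1 (adjusted p = 0.064, edgeR).

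The overlap extends beyond the list of 2-cell-stage genes, of which 24 of the 31 tested in both were higher in both. Such a short list cannot show whether the overlap reaches beyond the 2-cell programme as a whole. Across genes, which are not independent replicates, the log2 fold changes of the comparisons had a Pearson correlation of 0.305 and a Spearman correlation of 0.207, or 0.203 without the 2-cell-stage genes. Genes that moved in opposite directions numbered 153 higher after Ubc9 depletion and lower in H1 TKO cells, against 224 from independent lists, and 139 the other way, against 208. The counts from independent lists again take no account of expression level. Without Ubc9-depleted library 1, 512 genes were higher in both and 411 lower in both. Genes higher in both numbered 294 and 287 without Ubc9 control library 1 or 2, 318 and 308 without H1 TKO library 1 or 2, and 960 and 911 without H1 control library 1 or 2. In the same order genes lower in both numbered 206 and 193, 145 and 138, and 900 and 1096.

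Here the H1 effect is H1 TKO against control, so it includes any other difference between those lines. The comparisons also differ in library kit, and one sets 72 hours of doxycycline where the other uses a knockout. What these add to the differences below was not tested. Effects differed between the comparisons for 2464 of 16974 genes (edgeR quasi-likelihood test of the interaction, adjusted p under 0.05). Of these, 1372 were higher in the Ubc9 effect and 1092 higher in the H1 effect. The Rhox cluster was higher in the H1 effect, with a median difference of -2.68 in log2 fold change, Ubc9 minus H1 (limma camera adjusted p = 2.3e-06; adjusted p = 0.131 with an estimated correlation). Rhox5 differed by -2.26 ± 0.26, and 4 of 8 Rhox genes passed as higher in the H1 effect. Trophectoderm genes differed by -1.51 (limma camera adjusted p = 3.7e-04; adjusted p = 0.260 with an estimated correlation), with Krt18 at -3.18 ± 0.26 and 6 of 16 members higher in the H1 effect. Integrated stress response genes had a median difference of 0.61, with 8 of 25 members higher in the Ubc9 effect and 1 in the H1 effect (limma camera adjusted p = 0.0026; adjusted p = 0.646 with an estimated correlation), with Mthfd2, on chromosome 6, at 2.42 ± 0.22. Neuroectoderm genes differed by 1.39 (limma camera adjusted p = 0.0418; adjusted p = 0.554 with an estimated correlation), with Sox11 at 3.00 ± 0.27 but only 2 of 14 members higher in the Ubc9 effect and 1 in the H1 effect, and Y-linked genes by 2.62, with 3 of 4 higher in the Ubc9 effect (limma camera adjusted p = 8.2e-04; adjusted p = 0.554 with an estimated correlation). Naive pluripotency, SUMO pathway and ribosomal protein genes had median differences of -0.30, -0.07 and -0.45 (limma camera adjusted p = 0.0418, 0.0445 and 3.7e-04; adjusted p = 0.646, 0.728 and 0.770 with an estimated correlation), with Dppa3 at -1.77 ± 0.23. Single members passed as higher in the H1 effect in 3 of 20 naive, 3 of 22 SUMO pathway and 0 of 78 ribosomal protein genes, and none as higher in the Ubc9 effect. For the 2-cell-stage genes the difference of -0.34 did not pass (limma camera adjusted p = 0.311), and 2 members were higher in the Ubc9 effect and 4 in the H1 effect. Among single genes, H1f0 differed by -3.04 ± 0.25, Mest by 5.29 ± 0.23, Lin28a by 3.35 ± 0.28 and Pdzrn4 by -8.27 ± 0.58 (edgeR). Lefty2 (0.57 ± 0.28, adjusted p = 0.205), Mmp12 (-0.70 ± 0.79, adjusted p = 0.650) and Zscan4d (0.77 ± 0.57, adjusted p = 0.394) did not pass (edgeR). The count of differing genes was 1285 and 1928 without Ubc9-depleted library 1 or 2, and 5349 and 6145 without H1 control library 1 or 2.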

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

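Higher and lower genes after Ubc9 depletion (3479 and 2467) were 1100 and 483 with all 8 libraries in 1 fit, and lower genes were 1084 with library totals alone and 168 at 2-fold. In H1 TKO cells (1271 and 1247) they were 2205 and 2158 in the fit of all 8 libraries and 2534 and 2407 with GC offsets, and lower genes were 1895 without a filter. Genes higher in both comparisons (530) were 346 at 2-fold, and genes lower in both (381) were 64 at 2-fold and 700 with GC offsets. DESeq2 gave 2759 and 2309 genes after Ubc9 depletion and 1667 and 1696 in H1 TKO cells. With each library left out in turn, counts ranged from 1230 to 8428 (Ubc9 higher), 795 to 4610 (Ubc9 lower), 617 to 3994 (H1 higher), 488 to 4038 (H1 lower), 287 to 960 (higher in both), 138 to 1096 (lower in both) and 1285 to 6145 (effects that differ). With an estimated correlation the 2-cell-stage list had camera (limma) adjusted p of 0.0864 after Ubc9 depletion and 0.174 in H1 TKO cells.

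Directions turned for some lists and genes, and the cause was not tested. After Ubc9 depletion, with GC offsets, core pluripotency and ribosomal protein genes turned in direction (limma camera adjusted p = 0.8503 and 0.692) and naive genes passed (0.0426). Hox genes turned with fry (0.898). Of 78 ribosomal protein genes in H1 TKO cells, 1 was higher in the main fit, 9 with DESeq2 and 29 with GC offsets. With single libraries left out, the lists that turned after Ubc9 depletion had limma camera adjusted p from 0.129 to 0.891 for core pluripotency (0.129 turned), 0.289 to 0.944 for histone H1 genes (0.665 turned), 0.119 to 0.913 for Y-linked genes (0.913 turned), 2.8e-04 to 0.444 for core histone genes (0.0817 turned), 0.0021 to 0.981 for ribosomal protein genes (0.0021 and 0.672 turned) and 0.0878 to 0.986 for Hox genes (0.452 and 0.986 turned). In H1 TKO cells the ranges were 0.396 to 0.963 for imprinted genes (0.776 and 0.963 turned), 0.225 to 0.889 for SUMO pathway genes (0.586 turned), 0.127 to 0.769 for histone H1 genes (0.305 turned), 0.219 to 0.769 for G2/M genes (0.769 turned) and 0.305 to 0.769 for core histone genes (0.769 turned). The log2 fold change of Hist1h3f after Ubc9 depletion ranged from -6.46 without Ubc9-depleted library 1 to 6.94, and that of Rps19 from -0.032 without Ubc9-depleted library 2 to 0.70.

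Treating replicate numbers as a block gave 3160 and 2643 genes after Ubc9 depletion, 1732 and 1729 in H1 TKO cells, 620 and 512 in both and 2984 that differ. With the block, limma camera gave adjusted p = 0.0522 for formative and primed genes in H1 TKO cells, and 0.0747 for protocadherins and 0.0321 for naive genes after Ubc9 depletion, and edgeR gave 0.0504 for Klhl30 and 32 higher ribosomal protein genes in H1 TKO cells. Deviations of libraries with the same number had a Pearson correlation of 0.0174 (Ubc9) and 0.0565 (H1) and a Spearman correlation of -0.0177 and 0.153, so a weak pairing in the H1 libraries is not excluded.

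Of 117 named genes in the Ubc9 comparison, 23 lost their call with DESeq2, 8 with RLE factors, 12 and 7 without Ubc9-depleted library 1 or 2, and 59 and 60 without Ubc9 control library 1 or 2. Of 103 in the H1 comparison, 1 lost its call with DESeq2, 0 with RLE factors, 35 and 30 without H1 TKO library 1 or 2, and 3 and 0 without H1 control library 1 or 2. Of 48 other list results, 17 lost their call with an estimated correlation and 14 with fry, which gained 2.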

Other observations

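Gene families were examined by shared symbol, a search chosen after the results were seen, and some of their members also belong to the fixed lists. Of 519 families tested after Ubc9 depletion, 14 were higher and 3 lower, and of 468 tested in H1 TKO cells 1 was higher, the Rhox cluster, and 2 were lower (Fisher's exact test with Benjamini-Hochberg adjustment). Higher calls were more frequent among genes of low expression after Ubc9 depletion, so the families were tested again against genes of the same level group (10 equal groups by control mean), a test also chosen after the results were seen. Of the 17 families after Ubc9 depletion, only collagens then passed, and all 3 in H1 TKO cells did. The 3 lower families after Ubc9 depletion, with symbols Ddx, Kif and Nup, thus did not pass. They had 16 of 38, 15 of 36 and 10 of 21 members lower, where 10.4, 7.75 and 6.27 were expected at their level. Collagen genes were higher after Ubc9 depletion in 30 of 39 cases, with 13.9 expected at their level (exact test within level groups, adjusted p = 4.4e-05). Col11a1, a fibrillar collagen of cartilage, rose by 2.91 ± 0.12 on the log2 scale (± SE, edgeR) while Col9a2 fell by 0.73. With Ubc9-depleted library 1, Ubc9-depleted library 2, Ubc9 control library 1 and Ubc9 control library 2 left out in turn, 27 of 39, 40 of 44, 17 of 44 and 14 of 44 tested collagen genes rose. Cytochrome P450 genes rose in 30 of 44 cases where 18.7 were expected. All 6 tested genes with the symbol Tdrd, called Tudor-domain genes here, rose where 1.54 were expected. Neither family passed (exact test within level groups, adjusted p = 0.0753 and 0.0585). In the same order of libraries, 28 of 41, 79 of 87, 9 of 87 and 7 of 86 cytochrome P450 genes and 6 of 6, 6 of 7, 2 of 7 and 2 of 7 Tudor-domain genes rose.

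In H1 TKO cells 7 of 8 Hoxa genes, part of the Hox list and on chromosome 6, fell where 0.792 were expected at their level (exact test within level groups, adjusted p = 2.5e-04), with Hoxa5 down by 2.64 ± 0.38 on the log2 scale. That expectation is too low for chromosome 6, where 173 of 529 genes of at least 2 CPM fell, and it was not matched for chromosome. Of 6 kallikrein genes, on chromosome 7, 5 fell where 0.529 were expected (exact test within level groups, adjusted p = 0.0045), with Klk10 down by 1.31 ± 0.33. Of 6 genes in the Rhox family 5 rose where 0.761 were expected (exact test within level groups, adjusted p = 0.0455). Leaving out H1 TKO libraries 1 and 2 and H1 control libraries 1 and 2 in turn, 7 of 9, 4 of 9, 6 of 8 and 7 of 8 Hoxa genes and 3 of 8, 4 of 8, 5 of 6 and 6 of 7 kallikrein genes fell, and 5 of 6, 5 of 7, 5 of 7 and 5 of 7 Rhox genes rose.

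Patterns in the values had explanations tested against predictions written before the tests, except for H1 loss acting on chromosomes 6 and 8, whose prediction was written after the value was seen. At equal depth, Ubc9-depleted library 1 had reads on 84.4% of 6248 genes with at most 1 count in each Ubc9 control. Genomic DNA in the library is a candidate explanation: reads per exonic kilobase on the X chromosome were 0.556 (95% bootstrap interval 0.458 to 0.664) of those on autosomes in this male line, and counts rose with exonic length (Spearman correlation 0.511). Without symbol families that ratio was 0.732, with a 95% bootstrap interval that starts at 0.403 and includes 1. The X to autosome ratio of median reads per exonic kilobase, with symbol families kept, was 0.263. Leaky transcription from a single X chromosome could also lower these ratios. Derepression by Ubc9 depletion cannot be told apart, because the share of such genes with a read in Ubc9-depleted library 2 was 0.346 of that in library 1, between the limits set for and against it. A deeper library does not account for the reads, since at equal depth library 1 detected 19.5% more genes than the next.

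Genes of chromosomes 6 and 8 were lower in H1 TKO cells by a median of -0.535 relative to other autosomes, where loss of 1 of 3 copies would give -0.585. GC content does not account for this, since the difference was -0.537 (95% bootstrap interval -0.589 to -0.497) after the GC trend was removed. The prediction for a copy number difference between the lines covered both chromosomes together, with 4 stretches per chromosome. Those of chromosome 8 lay between -0.604 and -0.536, and all met the limit set for it. Those of chromosome 6 were uneven, at -0.292, -0.770, -0.793 and -0.176, the last short of that limit. A copy number difference therefore cannot be told apart for both chromosomes together, and chromosome 8 alone met its part of the prediction. Loss of H1 acting on these chromosomes likewise stays open, because no value here separates it from a karyotype difference between the lines. The same difference in Ubc9-depleted cells, which were not made to lack H1, was 0.00360 and does not bear on it. The calls for Mest, Mcm2, Mthfd2, Stra8 and Hoxa genes, all on chromosome 6, may carry part of this shift.

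Ribosomal protein genes differed between H1 control libraries 1 and 2, with a median log2 ratio of -0.589 against -0.134 between the H1 TKO libraries. GC content and gene length cannot be told apart as causes, because 70.3% of the ratio was left after the GC trend was removed and 50.4% after the length trend, each between the limits set for and against it. Across the 11241 genes with a mean of at least 2 CPM and a GC value, the ratio of the H1 control libraries had a Spearman correlation with GC content of -0.751. For the H1 TKO libraries it was -0.132. No biological explanation was tested.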
